A study of Homo sapiens with 6 samples.

How the data were processed

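RNA sequencing libraries were made from 6 human hip capsular biopsies, 3 taken at primary and 3 at revision total hip arthroplasty. Per the labels' protocols, the biopsies were snap-frozen, pulverised and homogenised, total RNA was purified with a column kit, samples were prioritised by RNA integrity, and libraries followed standard Illumina protocols. A characteristic in the labels names fibroblasts as the cell type, while the protocol describes whole tissue, so markers of other cell types were examined as well. Groups were taken from the labels' arthroplasty status and replicates were numbered within each group. These numbers pair no samples.

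Gene counts were deposited by the authors in a table of 23398 gene rows with chromosome, start, end and coding length. Per the submitters' processing notes, bcl2fastq, TopHat2 2.0.6, HTSeq and the hg19 genome were used. Their roles and settings, the annotation and the strand setting are not given in the sources used here. The counts were whole numbers and 100% of them were even, as they would be if each read pair had added 2 to its gene. How pairs were counted is not given in the sources used here, and counting intervals take a count of 2 as 1 read pair. RPKM values were deposited by the authors beside the counts. In each library they implied a single total larger than the sum over genes, of which genes held 80.8%, 83.3% and 63.5% in primary replicates 1 to 3 and 78.8%, 80.3% and 70.6% in revision replicates 1 to 3. Per the series' design text, the submitters compared RPKM values.

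Because the samples are human tissue, 123 rows of the Y chromosome and 2 rows of X-inactivation transcripts were removed before any test. A further 25 rows repeated another row's symbol and counts and were dropped, which left 23248 rows. Totals of counts ranged from 31431500 to 390994712, and up to 55874176 without primary replicate 3. A count of 3, the floor used for undetected genes, equals 0.0659 to 0.0914 CPM in primary replicates 2 and 1, 0.00772 CPM in primary replicate 3 and 0.0619 to 0.0875 CPM in revision libraries. As every count was even, a count of 3 cannot itself occur. If each read pair added 2, these floors lie below those that 3 read pairs would give. PCR reads are not independent molecules, so intervals and floors cover counting error only.

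Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM (factors 0.952, 1.01 and 0.998 for primary replicates 1 to 3 and 0.869, 1.09 and 1.09 for revision replicates 1 to 3), and glmQLFit and glmQLFTest compared revision with primary tissue without covariates. The test covered 16306 genes with 4 residual degrees of freedom, a prior of 3.81 degrees of freedom and a common dispersion of 0.251, a biological coefficient of variation of 0.501. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are revision minus primary, their standard errors were derived from the quasi-likelihood F statistic, and CPM values are TMM-scaled. The pairwise chi-square per degree of freedom of counts was at least 131 between libraries of a group, so that no pair agreed within sampling noise. Log2 fold changes showed no trend with coding length (Spearman rho -0.000549 across genes, which are not independent replicates).

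The named genes were the 12 with the highest and the 12 with the lowest log2 fold change among protein-coding genes past the threshold with groups that did not overlap and a mean log2 CPM of at least 3 (8 and 12 qualified). To these were added, for each list with a member past the threshold, its 3 members of lowest adjusted p, for each other list its 2 most abundant members, and the gene of highest mean expression. A fixed set of genes whose level can reflect genotype or sex was not named one by one. It held X-inactivation and Y-linked genes, certain polymorphic HLA and gene-deletion loci, and variable segments of antigen receptors. Other genes of this kind may be among those named. The rule, the 33 gene lists, the tests and the other settings listed below, save the last 3, were chosen before the data were examined. The lists hold 611 entries, of which 611 matched the table, 2 of them through older symbols in RefSeq's gene table of assembly GRCh38.p14, and 585 were tested. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, with camera and an estimated correlation, and with fry, whose p-value asks whether a list's genes move on balance one way without comparing them with other genes. Each was adjusted over the 33 lists. Scores of a list are means over its members of log2 CPM (prior count 2) centred on the member's mean over the 6 libraries.

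The alternatives were DESeq2 size factors, upper-quartile factors and library totals alone in the same edgeR test, DESeq2 1.42.0, limma-voom, limma on log2 RPKM with a pseudocount of 1 or 0.1 over genes with an RPKM of at least 1 in 3 libraries, no filter, a CPM of at least 1 in 3 libraries, robust dispersion, an adjusted p under 0.01 and each library left out in turn. Counts divided by 2, a thinning of primary replicate 3 to the median total of the others, and camera with an estimated correlation for the cell cycle list without revision replicate 2 were added after the data were seen. The tests were run on simulated counts with the real genes' means and library sizes and 200 changed genes among 16306. For revision against primary tissue edgeR recovered 22% of the 4-fold and 88% of the 16-fold changes, with 10 false calls among 120. DESeq2 recovered 63% and 94% with 85 false among 242, and limma-voom 20% and 82% with 5 false among 107. All 3 set tests recovered a raised list and called 0 of 20 unchanged lists. The simulated genes were drawn independently, so this could not show false calls that arise where members of a list vary together. In the real lists the estimated correlation was 0.449 for T cell markers and 0.810 for adipocyte markers.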

Results

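RNA sequencing measured gene expression in human hip capsular tissue, the synovium-lined capsule around the acetabulum, taken as biopsies at total hip arthroplasty. Of 6 libraries, 3 came from primary operations on hips labelled as never exposed to an implant metal, and 3 came from revision operations on hips labelled as exposed to cobalt-chromium, the alloy of metal-on-metal bearings. The series title places the comparison in the study of adverse local tissue reactions to such bearings. Total counts in genes were 34594208, 45000612 and 390994712 for primary replicates 1, 2 and 3, and 55874176, 39187572 and 31431500 for revision replicates 1, 2 and 3. Primary replicate 3 thus held 9.98 times the median total of the other 5 libraries. Every deposited count was even, as it would be if each read pair had added 2 to its gene, though how pairs were counted is not given in the sources used here. The labels do not say whether the samples came from separate donors, so the p-values measure the spread between these samples.

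The primary libraries resembled one another more closely than the revision libraries did. Spearman correlations of log2 CPM over 16306 genes lay between 0.955 and 0.965 within the primary group and between 0.880 and 0.927 within the revision group, and across groups they had a median of 0.897 (range 0.851 to 0.918). The first principal component held 41.0% of the variance and placed the primary libraries between -90.9 and -47.2 and the revision libraries between 19.5 and 109. Revision replicate 2 was the revision library nearest to the primary group on that component and lay at -105 on the second, which held 25.3%.

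CAMP, which encodes the antimicrobial peptide cathelicidin, rose from 0.400 ± 0.263 CPM in primary tissue to 25.2 ± 5.58 CPM in revision tissue (SD, n = 3 per group). MMP1, the interstitial collagenase, fell from 347 ± 129 CPM to 3.79 ± 2.46 CPM, and HHIP, a hedgehog-binding membrane protein, fell from 56.4 ± 2.46 CPM to nearly no reads. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 26 of 16306 genes passed an adjusted p of 0.05, 10 of them higher and 16 lower in revision tissue, a balance that other settings reversed, and all 26 differed by at least 2-fold.

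The named genes that rose did so between 7.20-fold and 64.1-fold. CAMP, on chromosome 3 at 48264837 to 48266981 (hg19), was 64.1-fold higher (adjusted p = 0.0246 by edgeR). CLEC4E, a C-type lectin receptor of macrophages, rose 17.2-fold, from 1.28 ± 0.372 to 21.9 ± 6.98 CPM. BCL2A1, an anti-apoptotic protein of blood cells, rose 18.8-fold to 78.8 ± 21.7 CPM, and CECR1, a secreted adenosine deaminase now called ADA2, rose 8.17-fold to 232 ± 84.7 CPM. APOBEC3A, an interferon-inducible cytidine deaminase, had 0.411 ± 0.220 CPM in primary and 20.5 ± 10.8 CPM in revision tissue. The deposited interval of APOBEC3A, on chromosome 22 at 39353527 to 39388783, is wide enough to reach its near-identical neighbour, so its reads are uncertain. DNAJC5B, a J-domain co-chaperone on chromosome 8 at 66933791 to 67012755, rose 63.2-fold (log2 5.98 ± 0.48, adjusted p = 0.0142 by edgeR). KLHL6, which acts in B cell receptor signalling, rose 9.91-fold, and BMP7, a bone morphogenetic protein, rose 7.20-fold to 14.6 ± 3.42 CPM. PDCD1, the inhibitory T cell receptor PD-1, rose from 0.374 ± 0.198 to 8.65 ± 1.18 CPM. It fell outside the naming rule on expression and was named after its values were seen. The remaining gene that rose is not named because its level can reflect a genotype.

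Genes that fell included HHIP, GDF5 and SMOC1. HHIP, on chromosome 4 at 145567148 to 145659881, had a count of 4 over the 3 revision libraries, all in revision replicate 3, which, taken as 2 read pairs, gives a ratio of 1769 between the primary mean and the pooled revision level (95% counting interval 490 to 14605). LOC646576, at 145564068 to 145567171 on the same chromosome, adjoins the start of HHIP and fell as well. GDF5, a growth factor of joint formation on chromosome 20 at 34021149 to 34026027, fell from 49.0 ± 24.9 to 0.525 ± 0.348 CPM. SMOC1, a secreted calcium-binding matrix protein, fell from 311 ± 175 to 4.99 ± 2.85 CPM. SEMA3A, an axon guidance signal, was 17.9-fold lower in revision tissue, and NPTX2, a neuronal pentraxin, was 9.03-fold lower. FZD8, a Wnt receptor, was 4.63-fold lower.

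MMP1, on chromosome 11 at 102660641 to 102668966, had a log2 fold change of -6.52 ± 0.66 (SE, adjusted p = 0.0352 by edgeR). COL6A5 and COL22A1, which encode collagen chains, were 88.3-fold and 44.4-fold lower in revision tissue. NID2, a basement membrane protein, fell from 115 ± 15.4 to 16.4 ± 6.98 CPM, and ENPP1, which makes extracellular pyrophosphate, fell from 178 ± 84.3 to 14.9 ± 1.93 CPM. HYAL1, a hyaluronidase, fell from 28.6 ± 2.36 to 7.32 ± 0.446 CPM. SCARA3, a scavenger receptor, and PSD, an exchange factor for a small GTPase, were 7.21-fold and 8.27-fold lower, and CDO1, a cysteine dioxygenase, was 5.98-fold lower. CDO1, FZD8, HYAL1 and LOC646576 fell outside the naming rule and were named after their values were seen.

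**Figure D1:**
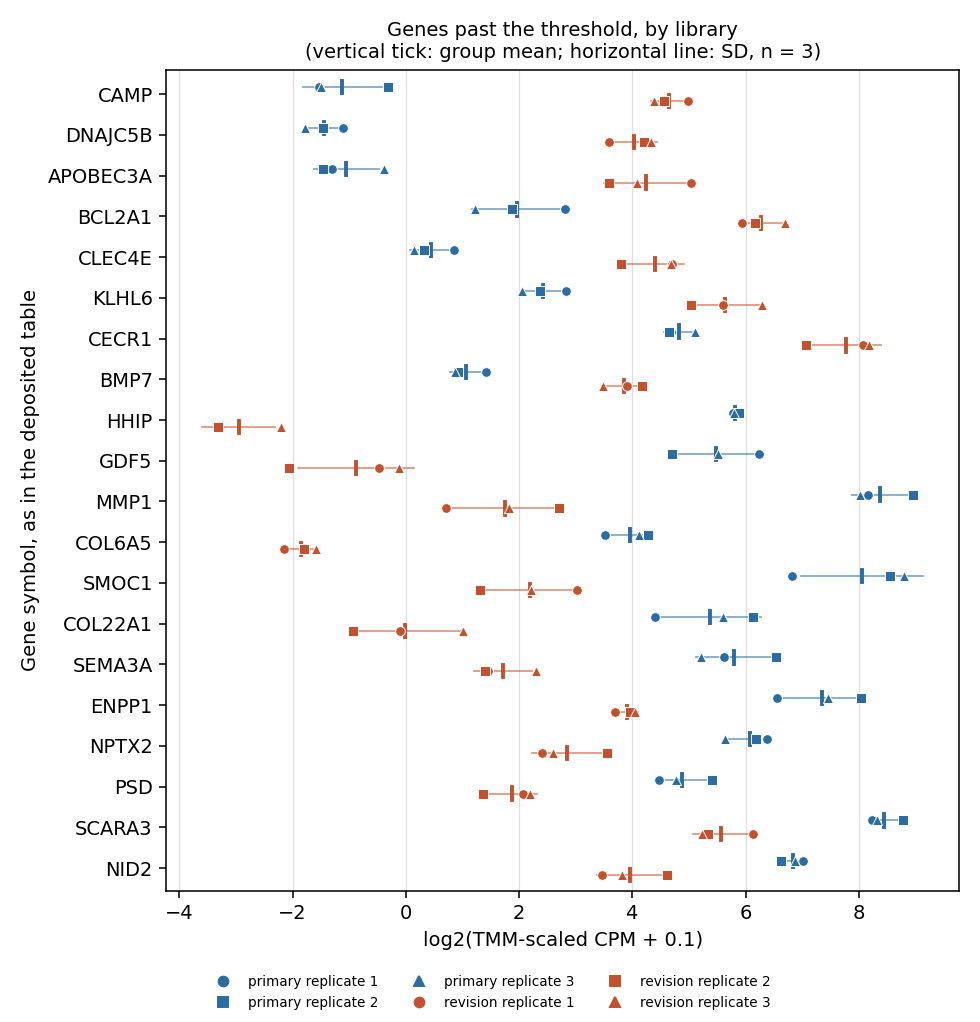
Levels of the 20 genes past the threshold that the naming rule took, by library, as log2 of TMM-scaled CPM plus 0.1; points are libraries, vertical ticks are group means and horizontal lines are SDs (n = 3). The 8 genes at the top, CAMP to BMP7, lie higher in all 3 revision libraries than in all 3 primary libraries, and the other 12 lie lower.

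The count of 26 and its majority of lower calls depended on single libraries and on the tool: edgeR called 0 genes without primary replicate 1 and 0 without primary replicate 3 (2284 and 1978 at an unadjusted p under 0.05), 1 without primary replicate 2, 7 and 13 without revision replicates 1 and 3, and 743 without revision replicate 2 (457 higher, 286 lower), whereas with all 6 libraries DESeq2 called 1642 (1006 higher, 636 lower), limma-voom 288 (169 and 119), and edgeR 73 with library totals alone (43 and 30) and 80 with the counts halved (41 and 39). Leaving out a library also lowers power, which these counts do not separate from an effect of that library. Of the 16306 genes, 1949 were higher and 1989 lower in every revision library than in every primary library, 24.2% in all. Chance gives 10% on average over groupings, but genes vary together, so a single grouping can lie far from it. The share was not taken for other groupings. An unadjusted p under 0.05 by edgeR was reached by 2926 genes.

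Scores of the B cell, T cell and NK gene lists were higher in all 3 revision libraries than in all 3 primary libraries, although no member of these lists passed the threshold over all genes. Single members such as CD28 (log2 -0.26), SDC1 (-0.31), KLRD1 (-0.20) and NCAM1 (-0.52) had negative fold changes with overlapping groups. The B cell and plasma cell list had a median log2 fold change of 3.29, and 12 of its 16 tested members passed when adjusted over the list alone. MS4A1, which encodes CD20, had 0.721 ± 0.366 CPM in primary and 19.7 ± 15.3 CPM in revision tissue (edgeR adjusted p = 0.0729), and the immunoglobulin J chain gene, IGJ, was 14.3-fold higher, at 67.4 ± 54.1 CPM in revision tissue. For T cell markers the median was 2.55, and 16 of 18 members passed when adjusted over the list alone, all of them higher. CD3D, a chain of the T cell receptor complex, had 3.30 ± 2.99 and 28.8 ± 10.9 CPM, and CD2, a T cell adhesion receptor, had 5.18 ± 3.34 and 32.4 ± 3.12 CPM. For NK and cytotoxic genes the median was 2.28, with 7 of 13 members past the threshold when adjusted over the list alone, among them GZMA, which encodes a granzyme, at 5.30 ± 3.66 and 27.4 ± 8.51 CPM. Camera with the preset correlation of 0.01 called these lists at adjusted p = 6.38e-09, 3.39e-11 and 5.21e-05 for B cell, T cell and NK genes. None held with an estimated correlation, where the adjusted p was 0.305, 0.305 and 0.351 in that order. List members named here and below beyond the rule for named genes, such as MS4A1 and CD3D, were chosen after their values were seen.

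All 23 interferon-response genes had a positive fold change, with a median of 2.06, and 19 of 23 passed when adjusted over the list alone. IFI27 had 185 ± 43.0 CPM in primary and 1153 ± 1131 CPM in revision tissue, and CXCL9, a T cell-attracting chemokine, had 0.808 ± 0.328 and 32.8 ± 35.6 CPM. The chemokine and receptor list had a median of 1.84, with 13 of 27 members past the threshold when adjusted over the list alone. CCL18, a chemokine of alternatively activated macrophages, was 15.9-fold higher, at 103 ± 53.6 and 1643 ± 359 CPM (edgeR adjusted p = 0.0514). CXCL12, a chemokine of stromal cells, went the other way, at 443 ± 105 and 248 ± 83.0 CPM. Inflammatory cytokines had a median of 1.24, with 6 of 18 members past the threshold when adjusted over the list alone. CSF1 and NFKBIA, the most abundant of them, had 2.21-fold and 2.26-fold higher means, largely through revision replicate 2. In revision replicates 1 to 3 CSF1 had 92.5, 391 and 114 CPM and NFKBIA had 94.6, 345 and 127 CPM. The highest primary values were 108 and 88.2 CPM, so the groups overlapped for CSF1. Camera with the preset correlation gave adjusted p = 3.90e-11, 2.48e-07 and 0.000807 for interferon-response genes, chemokines and cytokines. The calls did not hold with an estimated correlation, at adjusted p = 0.305, 0.305 and 0.429 in that order. Scores of both the interferon and the chemokine list were highest in revision replicate 2, where the chemokine score was 1.51. The cytokine score was highest there too, at 1.71 against -0.14 and 0.27 in revision replicates 1 and 3. Its groups overlapped, as primary replicate 3 had -0.07.

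All 12 genes of MHC class II presentation had a positive fold change (median 1.26), and 10 of 12 passed when adjusted over the list alone. CD74, the class II invariant chain, had 2875 ± 578 and 7053 ± 1653 CPM, and HLA-DRA had 1546 ± 134 and 2965 ± 494 CPM. Inflammasome and Toll-like receptor genes had a median of 0.84, and CASP1, AIM2 and TLR9 passed when adjusted over the list alone (3 of 18). Dendritic cell markers had a median of 0.85, with CLEC10A, a lectin of dendritic cells, and CCR7, their lymph-node homing receptor, past the threshold when adjusted over the list alone (2 of 11). Adjusted p-values by camera with the preset correlation were 2.48e-07, 4.15e-05 and 0.0163 for these lists. With an estimated correlation the adjusted p was 0.305, 0.305 and 0.474.

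Monocyte and macrophage markers had a median of 0.40. LYZ, which encodes lysozyme, alone passed when adjusted over the list alone (1 of 20). CD68 had 1126 ± 392 and 2831 ± 1361 CPM, whereas C1QA had 1228 ± 396 and 1577 ± 599 CPM with overlapping groups. Lysosome and phagocytosis genes had a median of 0.61 with 6 of 24 past the threshold when adjusted over the list alone, among them CTSD, the protease cathepsin D, at 1697 ± 581 and 11653 ± 9062 CPM. Oxidative stress genes had a median of 0.65, and 4 of 20 passed when adjusted over the list alone, among them GCLC, which encodes a subunit of the enzyme that makes glutathione precursors, and SOD2, the mitochondrial superoxide dismutase. Adjusted p-values by camera with the preset correlation were 0.0182, 0.000262 and 0.00400 for macrophage, lysosome and oxidative stress genes. With an estimated correlation the adjusted p was 0.529, 0.332 and 0.305.

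FTL, the ferritin light chain, had the highest mean expression of any gene, at 13886 ± 2753 CPM in primary and 46682 ± 20392 CPM in revision tissue (log2 1.75 ± 0.62 SE, edgeR adjusted p = 0.198). It took 1.62%, 1.32% and 1.17% of the counts of the primary libraries and 4.90%, 2.54% and 6.60% of those of the revision libraries. FTH1, the heavy chain, had 4977 ± 2014 and 14909 ± 4163 CPM. In the iron and haem list, of median 0.61, HAMP, the iron hormone hepcidin, alone passed when adjusted over the list alone (1 of 16). Camera with the preset correlation gave an adjusted p = 0.0182 for the list, and the adjusted p was 0.305 with an estimated correlation.

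Metallothioneins are small metal-binding proteins that zinc and other metals induce. The metallothionein and zinc transport list had a median of -1.42, and MT1A, MT1E, MT1F, MT1M, MT1X and MT2A passed, all lower, when adjusted over the list alone (6 of 15). MT2A had 794 ± 176 CPM in primary and 245 ± 91.7 CPM in revision tissue (log2 -1.70 ± 0.40 SE, edgeR adjusted p = 0.0913). These genes are near-identical copies, so reads may be split between them, but their summed level, over 9 tested genes, was 1174 ± 296 CPM against 362 ± 114 CPM and did not overlap between groups. SLC39A14, a zinc and iron importer, had 250 ± 18.3 and 70.5 ± 68.5 CPM. Camera with the preset correlation gave adjusted p = 0.00122 for the list, and the adjusted p was 0.305 with an estimated correlation.

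Fibroblast and synovial lining markers had a median of -1.42 and scores that were lower in all 3 revision libraries. PDGFRA, FAP, HAS1, CD55, VCAM1 and GREM1 were lower and DPP4 was higher when adjusted over the list alone (7 of 19 in all). PRG4, the joint lubricant lubricin, had 6960 ± 4884 and 890 ± 877 CPM, and CD55, a marker of the synovial lining, had 1072 ± 994 and 81.9 ± 69.3 CPM. Matrix proteases and inhibitors had a median of -0.60. MMP1 passed over all genes, and MMP1, MMP3, MMP11, MMP13, TIMP1 and TIMP3 were lower when adjusted over the list alone (6 of 22). MMP13, a collagenase, had 257 ± 334 and 1.81 ± 1.93 CPM, and the inhibitor TIMP3 had 3424 ± 1899 and 535 ± 229 CPM. Of the fibrillar collagen and matrix genes, 22 of 23 had a negative fold change, with a median of -0.98, and 0 passed when adjusted over the list alone. FN1, which encodes fibronectin, had 20664 ± 4228 and 5886 ± 5527 CPM, and COL3A1 had 10920 ± 5211 and 3827 ± 5063 CPM. The collagen score of revision replicate 2 was 0.63, within the primary range of 0.38 to 1.12.

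Camera with the preset correlation called the fibroblast, protease and collagen lists at adjusted p = 0.000188, 0.00143 and 3.48e-05. With an estimated correlation the adjusted p was 0.305, 0.332 and 0.474. Cartilage and bone matrix genes (median -0.95, 0 of 17 past the threshold when adjusted over the list alone), smooth muscle and pericyte markers (median -1.07, 2 of 14, RGS5 and CSPG4) and red cell markers (median -1.60, 0 of 9) were lower as lists too, at adjusted p = 0.0117, 0.00288 and 0.0107. Each of these had an adjusted p = 0.474 with an estimated correlation. COMP, a cartilage matrix protein, had 1554 ± 316 and 806 ± 797 CPM, TAGLN, a smooth muscle protein, had 755 ± 290 and 349 ± 329 CPM, and HBB, a globin chain, had 1661 ± 1443 and 444 ± 385 CPM, all with overlapping groups.

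**Figure D2:**
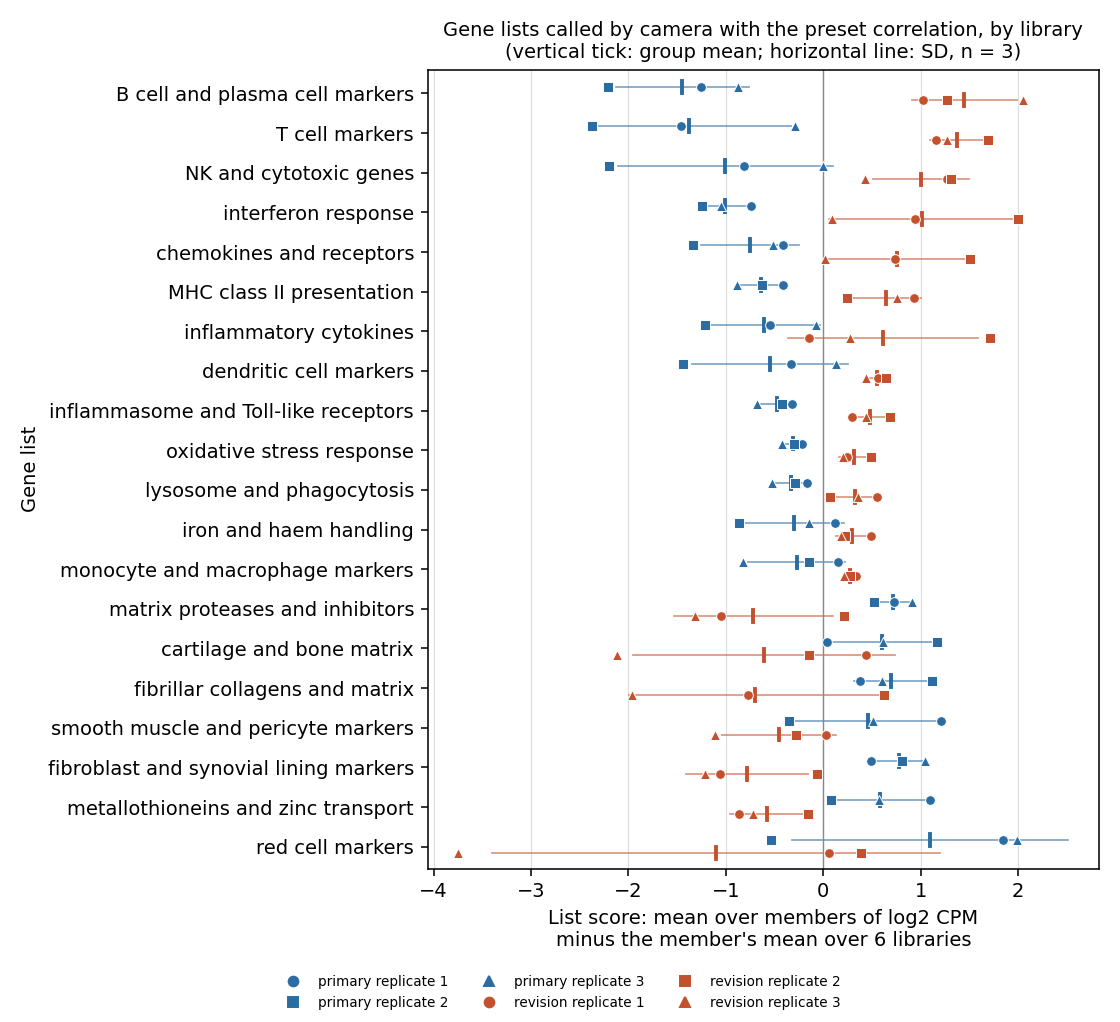
Scores of the 20 gene lists that camera called with the preset correlation, by library, each the mean over members of log2 CPM minus the member's mean over the 6 libraries; points are libraries, vertical ticks are group means and horizontal lines are SDs (n = 3). The T cell score lies between -2.37 and -0.29 in the primary libraries and between 1.16 and 1.69 in the revision libraries, whereas the collagen score of revision replicate 2 (0.63) lies among those of the primary libraries.

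Camera with the preset correlation did not call 13 of the 33 lists. Osteoclast and giant cell genes had a median of 1.14 (adjusted p = 0.0980), and ATP6V0D2, OSCAR and GPNMB were higher when adjusted over the list alone (3 of 18). Neutrophil markers had a median of 1.07 (adjusted p = 0.153). CAMP passed over all genes, and CAMP and CSF3R, the receptor of a granulocyte growth factor, passed when adjusted over the list alone (2 of 14). Neutrophil scores were 1.23, 1.31 and -1.25 in revision replicates 1 to 3, the last of them below every primary library. The hypoxia list had a median of 0.53 (adjusted p = 0.121), with ADM, which encodes the vasodilator adrenomedullin, higher when adjusted over the list alone (1 of 24). Its score was 1.49 in revision replicate 2 and -0.48 and -0.40 in revision replicates 1 and 3, and the median was -0.27 without revision replicate 2. Nerve and Schwann cell markers had a median of 0.27 (adjusted p = 0.519). MBP and NEFL were higher and PMP22 was lower when adjusted over the list alone (3 of 10 in all).

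No member passed, even when adjusted over the list alone, in the other 9 lists. The cell cycle list had a median of 0.50 (adjusted p = 0.612), which turned to -0.54 without revision replicate 2, where camera called it lower with the preset correlation (adjusted p = 0.0392) but not with an estimated correlation (adjusted p = 0.650). Medians were 0.41 for apoptosis and p53 targets (adjusted p = 0.118), -0.18 for the mitochondrial respiratory chain (0.151), -0.29 for Wnt and TGF-beta signalling (0.0938) and -0.87 for skeletal muscle markers (0.707), the last of which was 1.14 by limma-voom. Mast cell, adipocyte and endothelial markers had medians of 0.01, -0.02 and -0.02 (0.725, 0.178 and 0.663), each of which changed sign under another scaling. For endothelial markers the mean was 0.11, of the opposite sign to the median and to the camera direction. Immediate early and heat shock genes had a median of -0.06, which changed sign with library totals alone, while their mean of 0.31 and the camera direction were positive (0.781). CDKN1A, a p53 target that halts the cell cycle, had 117 ± 16.2 and 224 ± 37.2 CPM with groups that did not overlap.

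Over all 33 lists, camera with the preset correlation called 20, of which 13 were higher and 7 lower, but with an estimated correlation it called 0, with 3 at an unadjusted p under 0.05, and fry called 4, namely B cell and plasma cell markers, MHC class II presentation, inflammasome and Toll-like receptors, and oxidative stress response, each at adjusted p = 0.0468. List scores of the groups did not overlap for 13 lists higher and 4 lower in revision tissue, where chance gives 10% on average for a single list. The lists were scored in the same libraries and are not independent, so the number of such lists can lie far from that share. An exact two-sided permutation test of 3 against 3 cannot go below p = 0.1.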

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

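Halving the counts, thinning primary replicate 3 and estimating the correlation without revision replicate 2 were chosen after the data were seen, and the other alternatives were planned. All 26 called genes kept their direction under every alternative that gave them a value (25 of 25 under RPKM), but the count did not hold. It was 38 with DESeq2 size factors in edgeR (17 higher and 21 lower), 26 with upper-quartile factors, 27 with robust dispersion and 27 with primary replicate 3 thinned, and these held 26, 25, 26 and 26 of the 26 genes. It reached 73 with library totals alone (43 higher, 30 lower), 1642 by DESeq2 (1006 higher, 636 lower, 1569 with at least a 2-fold change), 288 by limma-voom (169 and 119), 294 by limma on log2(RPKM + 1) (184 and 110, 293 at least 2-fold), 211 on log2(RPKM + 0.1) (136 and 75), 259 without a filter (149 and 110), 61 with a CPM of at least 1 in 3 libraries (30 and 31) and 80 with the counts halved (41 and 39). At an adjusted p under 0.01 edgeR called 0 genes, with 2926 at an unadjusted p under 0.05, and the other tools were run at 0.05 alone. The higher share of the calls, 38.5% as reported, was 58.9% with library totals alone, 61.3% by DESeq2, and 62.6% and 64.5% on RPKM. Leaving out 1 library gave 0 to 743 genes (0 to 457 higher, 0 to 286 lower, 0 to 743 at least 2-fold), with 0 genes without primary replicate 1 or 3, 1 without primary replicate 2, 7 and 13 without revision replicates 1 and 3, and 743 without revision replicate 2. The cause was not tested. Adjusted p-values of CAMP ran from 3.04e-28 to 0.0848 over 19 alternatives and those of MMP1 from 2.41e-29 to 0.0848. The median correlation across groups was 0.837 on both RPKM scales, 0.933 without a filter and 0.868 with the CPM filter. Of the 20 lists called, 0 held with an estimated correlation and fry called 4. With the preset correlation, 5 lost their call at an adjusted p under 0.01, 3 on each RPKM scale and 2 with the CPM filter. Leaving out 1 library ended 1 to 4 of the calls, the most without revision replicate 2. No called gene and no called list reversed. Reversals were of genes and lists that had not been called as reported, and their cause was not tested. Adipocyte markers had medians of 0.025 with DESeq2 size factors in edgeR and by DESeq2, 0.015 with the CPM filter and 0.023 with primary replicate 3 thinned. Mast cell markers had medians of -0.00071 with library totals alone, -0.45 by limma-voom, -0.14 and -0.075 on log2(RPKM + 1) and log2(RPKM + 0.1), -0.0091 without a filter and -0.032 with the CPM filter. Endothelial markers had medians of 0.088 with library totals alone and 0.051 by limma-voom. Immediate early and heat shock genes had medians of 0.056 with library totals alone, 0.12 by limma-voom, and 0.12 and 0.13 on the RPKM scales. Limma-voom also reversed skeletal muscle markers (1.14), nerve and Schwann cell markers (-0.036) and ENO1 (-0.014). HPGDS was -0.00071 with library totals alone, -0.0035 by limma-voom, -0.0020 on log2(RPKM + 1) and -0.0091 without a filter. With 1 library left out, lowest and highest medians were -4.61 and 0.76 for adipocyte, -0.46 and 0.84 for mast cell, -0.78 and 0.66 for endothelial, -0.91 and 0.48 for immediate early and heat shock, -0.098 and 0.71 for nerve, -0.27 and 0.83 for hypoxia and -0.54 and 0.83 for cell cycle genes, the hypoxia and cell cycle minima without revision replicate 2, where the cell cycle list was called lower (camera adjusted p = 0.0392, but 0.650 with an estimated correlation). Fold changes of single genes then ran from -0.46 to 0.30 for HPGDS, -1.61 to 0.18 for CILP, -0.51 to 1.58 for CFD, -0.014 to 3.78 for TNNT3, -0.12 to 0.45 for COX4I1, -0.038 to 0.55 for ALDOA, -0.36 to 0.36 for ENO1, -1.23 to 0.10 for SDC1, -5.74 to 0.67 for FABP4 and -0.63 to 0.45 for MCL1. HHIP, with a count of 4 in revision tissue, ran from -15.62 to -3.66 over the alternatives, and COL6A5, with few reads there, from -6.68 to -6.24.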

Other observations

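The tests of causes below were chosen after the result was seen, except the share of genes at which revision replicate 2 lay nearer to its own group and the splits of the list count. Genes in the next 2 paragraphs were picked after their values were seen. CSN1S1, which encodes a casein of milk, stood at 17002, 1976 and 514 CPM in primary replicates 1 to 3, and at 0.825, 0.421 and 1.98 CPM in the revision libraries (edgeR adjusted p = 0.0514, log2 -12.57 ± 1.84 SE). MMP3, the matrix protease stromelysin, had 1119 ± 1002 and 6.02 ± 6.40 CPM (adjusted p = 0.0823). CXCL13, a B cell-attracting chemokine, had 0.750 ± 0.680 and 32.0 ± 47.4 CPM, and CTLA4, an inhibitory T cell receptor, had 0.275 ± 0.439 and 7.37 ± 5.29 CPM, neither past the threshold over all genes (edgeR adjusted p = 0.117 and 0.138).

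The monocyte and macrophage scores of revision replicates 1 to 3 lay close together, at 0.34, 0.28 and 0.21, but some genes of such cells did not. CHIT1, a chitinase of lipid-laden macrophages, had 5332 and 4775 CPM in revision replicates 1 and 3 and 8.48 CPM in revision replicate 2, and ACP5, the tartrate-resistant phosphatase of osteoclasts, had 2994, 1544 and 226 CPM in the same order. SPP1, which encodes osteopontin, was highest in revision replicate 2, at 169, 55.1 and 7232 CPM in that order. The hypoxia score was 1.49 in revision replicate 2 and between -0.48 and -0.12 in the other 5 libraries. Adipocyte content cut across the groups, with scores of 1.86, -2.41 and 2.84 in primary replicates 1 to 3 and 2.98, -3.45 and -1.83 in revision replicates 1 to 3. PLIN1, a lipid droplet protein of adipocytes, ran from 0.328 to 104 CPM over the 6 libraries.

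The T cell score was 2.75 ± 0.62 (SE) higher in revision tissue. If fewer connective tissue cells in the biopsies raised all other markers, endothelial markers would rise alike. The T cell score minus the endothelial score still differed by 2.91 ± 0.75 (SE). This comparison cannot decide the point, because endothelial cells lie in the same tissue and may be lost with it. The endothelial score also ran from -1.23 to 0.83 over the revision libraries. Blood left in the tissue would raise HBB with the T cell genes, whereas the log2 change of HBB minus that of the T cell score was -5.27 ± 2.15 (SE). The depth of primary replicate 3 would not account for it, since the list's median was 3.23 without that library and 2.55 with it. Other immune cells would rise alike too. B cell and NK scores rose by 2.89 and 2.01. The macrophage score rose by only 0.55 (SD 0.50 in primary and 0.07 in revision libraries). The mast cell score rose by 0.04 (SD 1.24 and 1.26). Unless macrophages were lost with the tissue, this argues against fewer connective tissue cells as the whole cause. A greater T cell content or activity in the revision group remains as a hypothesis, as do fewer connective tissue cells as part of the cause. Whether either may follow from metal exposure, revision surgery or implant failure was not tested, because the labels join these in 1 group.

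Revision replicate 2 stood apart from the other revision libraries. Of 743 genes called without it, it lay nearer to those libraries at 46.7%. This was under the 50% bound set beforehand for a primary sample with a wrong label. It also fell short of the higher bound set beforehand for rejecting a wrong label. A held-out comparison was added after this was seen, since the 50% bound appeared too lenient. Each primary library was held out in turn together with revision replicate 2, and as many genes were taken by p. The held-out primary library lay nearer to the revision libraries at 5.79% to 10.2% of these genes. Revision replicate 2 did so at 49.3% to 50.7%, which argues against a wrong label. An admixture of tissue like that of the primary group would leave it between the groups. Of the 33 list scores of revision replicate 2, hypoxia lay furthest above the other 5 libraries and was chosen after this was seen. It was 1.61 above the highest of these (SD of these 0.14), which argues against admixture as the whole cause. Admixture as part of it stays open, since genes called higher without it had a median position of 0.45 from the primary (0) to the other revision libraries (1), and although its T cell score was 0.42 above the higher of these, the T cell content of the unmixed tissue is unknown. A stress response before freezing is a candidate explanation for part of it. The immediate early and heat shock score of revision replicate 2 was 1.02 above the highest of the other 5 libraries (SD of these 0.61). Its cytokine, interferon and cell cycle scores also lay above all of these, by 1.44, 1.06 and 0.91, so the score does not single out stress. A difference between patients or in the stage of the tissue reaction was not tested.

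The lower metallothionein level is of interest because metals induce these genes. Reads split between near-identical copies would leave their sum alike, but the summed CPM of revision tissue was 0.309 times that of primary tissue, without overlap. Log2 summed metallothionein CPM minus the fibroblast score differed by -0.16 ± 0.51 (SE), against -1.72 ± 0.37 before that subtraction. Fewer fibroblasts thus remain a candidate explanation, but the subtraction cannot single them out. Protease and collagen scores fell by similar amounts (-1.44 and -1.40, against -1.56 for fibroblasts). In revision replicates 1 to 3 the summed CPM was 232, 410 and 445, which did not follow the fibroblast scores of -1.06, -0.06 and -1.22. A true change per cell was not tested.

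Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real one, which was the real split itself, with 26 genes against a highest other of 5, and for genes with at least a 2-fold change it was likewise 1, with 26 against 5. The split with 5 genes set primary replicates 1 and 3 with revision replicate 1, the 3 libraries with positive adipocyte scores. For lists called by camera with the preset correlation, 2 of the 10 splits gave 20 lists, the real one and one that set primary replicate 1 with revision replicates 1 and 2, and the other splits gave 7 to 18. With 10 splits a share under 0.05 cannot be reached.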
